A study of Homo sapiens with 6 samples.

How the data were processed

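Total RNA from 6 samples of the human oral squamous cell carcinoma line OSC19SSZR was sequenced, 3 after control siRNA and 3 after FOXA1 siRNA, delivered with a lipid transfection reagent 48 h earlier. Libraries were made with the NEBNext Ultra RNA kit, per the labels' protocols. The sources used here do not state whether the library kept strand information, how rRNA was removed or how reads were counted, so reads from a gene and an overlapping antisense gene could not be told apart. Per the submitters' processing notes, HISAT2 and DESeq2 and the builds GRCh38 and GRCm38 were named, without versions or roles. The gene IDs of the table are human Ensembl IDs, and 61756 of 61859 matched the human gene name table.

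The deposited table holds, per the file headers, 1 normalized signal value per gene and sample, which is a gene count divided by a size factor of the sample. The authors' mean signal per gene equals the mean of the 6 sample values to within 5e-05. The table also holds the authors' log2 fold change with its standard error on the log2 scale, a test score per gene, and the p-value and adjusted p-value. Of 61862 lines, 3 were malformed (1 gene without values and 2 broken lines) and were left out, and 27396 genes had no reads in any sample. In every sample, 100% of the values were whole multiples of a single step to within 0.01 read, so the reads behind them could be recovered. Recovered reads ranged from 16510125 to 25732569 per sample and the size factors from 0.843 to 1.32. Replicate libraries of a group differed by more than sampling noise (chi-square per gene 2.54 to 5.21), so none was a duplicate of another.

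Groups came from the sample titles. The main test was limma 3.58.1 in R 4.3.3 on log2(normalized count + 1), with lmFit and with eBayes using its trend and robust options, on the 18460 genes with a mean normalized count of at least 10 over the 6 samples. Benjamini-Hochberg adjustment was used with a threshold of 0.05, and fold changes of low genes are understated on this scale. The test, the lists of genes, the rule for named genes and the alternatives were chosen before the data were examined. In total 42 lists of genes were fixed, of which 40 had at least 5 tested genes and were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 40 lists. Camera with an estimated correlation and fry were run beside it, and the ranges given over a list's alternatives leave both out. A list's counts adjusted over the list alone differed from those over all genes for 18 lists, by at most 2 members. FOXA1 was also tested with an exact permutation test.

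Named genes were FOXA1, the 12 largest rises and the 12 largest falls among genes past the threshold with a mean of at least 50, a symbol that is not a clone, LOC, LINC, Ensembl or antisense name and no overlap between the groups. From each list described, up to 2 genes that rose and up to 2 that fell were taken by the size of their change, among members with a mean of at least 50. SLC7A11, GPX4, GCLC, GCLM, ALDH3A1, AKR1C1, NQO1, CD44, ABCG2, TP63, FOXA2 and FOXM1 were included whatever their result.

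Alternatives were pseudocounts of 0.5 and 5, no filter on low values, a mean of at least 50, equal library totals, quantile normalization, median-of-ratios factors recomputed on the tested genes, limma without its trend and robust options, the replicate number as a block, each sample left out in turn, a threshold of 0.01, and edgeR 4.0.16 (quasi-likelihood test with TMM factors) and DESeq2 1.42.0 on the recovered reads. Limma-voom on the recovered reads and a count over protein-coding genes alone were added after the data were seen. EdgeR on the recovered reads called 9653 genes and DESeq2 8493.

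The steps were tested on simulated data. Counts for the 18460 genes were drawn with the means, dispersions and library sizes of this comparison. In this draw 200 genes were changed, all with a mean of at least 50. Limma called 57 of 67 genes changed by 1.5-fold, 67 of 67 changed by 2-fold and 66 of 66 changed by 4-fold, and 13 unchanged genes. Detection at a mean of 10 to 50 was not tested. Far more genes were called in the real data (9571), so these rates do not describe a comparison with that many changes. Camera called the list moved by 1.3-fold and 0 of 37 lists that shared no member with it. Each gene was drawn independently, so the simulation did not test camera where members of a list are correlated. In the real data the estimated correlation reached 0.46 for the cytosolic ribosome list.

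Transcript length, GC content and 3' UTRs were taken from GENCODE release 29 (GRCh38), with the longest transcript and the longest 3' UTR per gene. A search for 7-base words compared the log2 fold changes of genes with and without each word in 3' UTRs of at least 50 bases, by linear regression with the UTR length, its base composition and the expression level as covariates, in Python 3.11.15 with numpy 2.4.6. It covered 12992 genes and 16142 words found in at least 100 genes. The t values were centred on their median and divided by their scale over all words, and the bound for a z over all words was 4.66. Figures were drawn with matplotlib 3.10.9.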

Results

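Gene expression was measured by RNA sequencing in OSC19SSZR cells, an oral squamous cell carcinoma line that is resistant to sulfasalazine, a drug that blocks cystine uptake through the transporter xCT. Cells received control siRNA (n = 3) or siRNA against FOXA1 (n = 3), a forkhead transcription factor that opens chromatin in many epithelia, and RNA was collected 48 h later. The comparison asked how the transcriptome of these resistant cells differs after FOXA1 knockdown. The reads recovered from the deposited normalized counts came to 19233157, 17923190 and 17286040 for control siRNA replicates 1, 2 and 3, and to 17888212, 25732569 and 16510125 for FOXA1 siRNA replicates 1, 2 and 3. The labels do not say whether the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

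FOXA1 (ENSG00000129514; GRCh38 chromosome 14, 37589984 to 37596059, minus strand, protein-coding) was lower in each of the 3 FOXA1 siRNA libraries. Its normalized counts were 1477, 1378 and 1459 with control siRNA and 247, 192 and 189 with FOXA1 siRNA, or 1438 ± 52.8 (SD, n = 3) against 209 ± 32.5 (SD, n = 3). The log2 fold change was -2.79 ± 0.09 (SE; limma adjusted p = 3.32e-18), which left 14.5% of the control level. An exact two-sided permutation test of the 6 values gave p = 0.1, the smallest value that 3 against 3 samples allow. Among the 20 tested members of the forkhead family, FOXA1 itself included, 3 rose and 8 fell (4 and 9 adjusted over the list alone). The list as a whole did not pass (camera adjusted p = 0.159). FOXM1, a driver of mitotic genes, rose (log2 fold change 0.54 ± 0.06) and so did FOXO1 (0.50 ± 0.10), while FOXN3 fell (-0.69 ± 0.09). FOXA2, the closest relative of FOXA1 named here, was at 64.9 ± 4.79 and 52.8 ± 2.58 normalized counts (SD, n = 3 each), a difference that did not pass (log2 fold change -0.29, limma adjusted p = 0.193). It passed as lower with limma without its trend and robust options (adjusted p = 0.0254, within a range of 0.0254 to 0.602 over its alternatives).

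**Figure D1:**
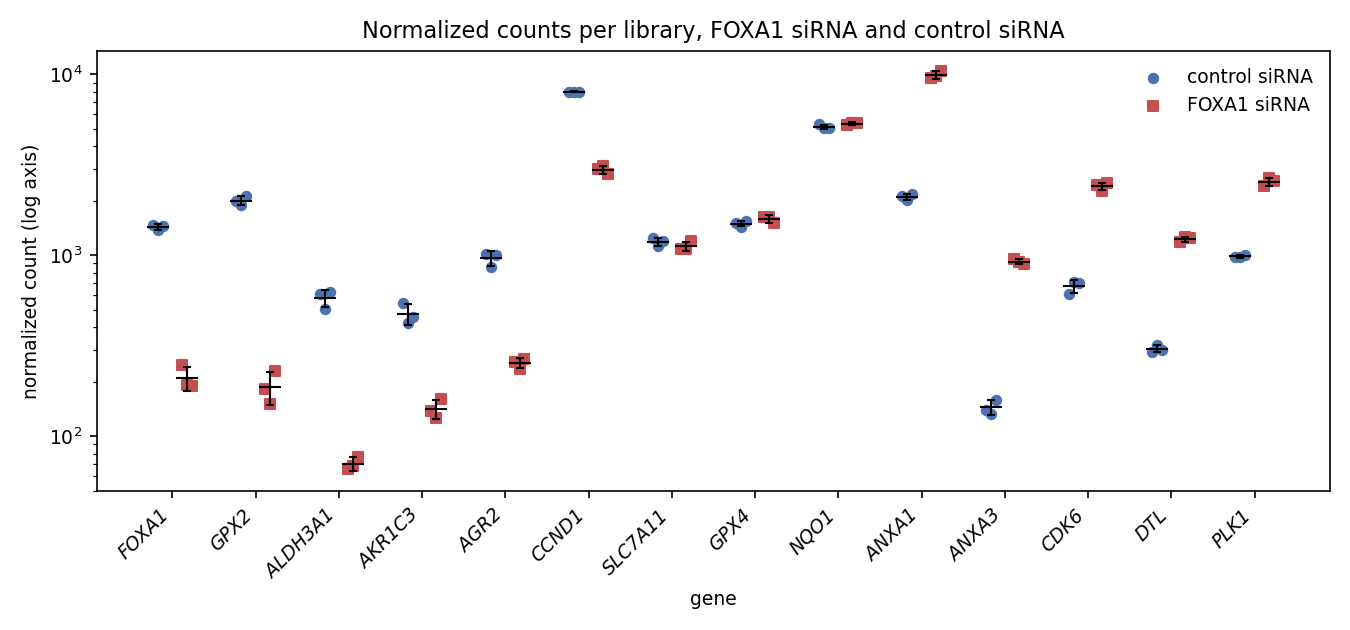
Normalized counts (log axis) of 14 named genes in each of the 3 control siRNA libraries (circles) and the 3 FOXA1 siRNA libraries (squares), with black bars for the mean and SD. FOXA1, GPX2, ALDH3A1, AKR1C3, AGR2 and CCND1 lie lower with FOXA1 siRNA, ANXA1, ANXA3, CDK6, DTL and PLK1 lie higher, and the values of SLC7A11, GPX4 and NQO1 overlap between the groups.

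Knockdown was accompanied by changes across much of the transcriptome. ANXA3 went from 144 ± 13.4 to 923 ± 25.5 normalized counts (SD, n = 3 each, log2 fold change 2.68 ± 0.09) and ANXA1, a calcium-dependent phospholipid-binding protein, from 2102 ± 74.0 to 9929 ± 481 (2.24 ± 0.05). CDK2 (1.90 ± 0.08) and CDK6 (1.83 ± 0.06), kinases of the G1 phase and S phase, also rose, as did DTL (2.01 ± 0.07), a substrate adaptor of the CUL4 ubiquitin ligase. The other 7 of the 12 largest rises were the peptide hormone gene APLN (2.36), the placental alkaline phosphatase gene ALPP (2.11), GEMIN5 (2.08), the carboxypeptidase gene CPA4 (2.05), DSEL (1.80), RPIA (1.76), an enzyme of the pentose phosphate pathway, and KRT16P6 (2.38). KRT16P6 is a keratin pseudogene whose reads the counting could have shared with its parent gene, so its value is uncertain.

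The 12 largest falls among the genes eligible for naming were led by SPDEF. This gene, a transcription factor of secretory epithelia, had 165 ± 4.98 normalized counts with control siRNA and 1.11 ± 1.07 with FOXA1 siRNA (SD, n = 3 each). Only 3 reads remained across the 3 knockdown libraries against 494 in the controls, a ratio of 170 (exact 95% interval 57.8 to 827, for counting error only). GPX2, a selenium-dependent glutathione peroxidase, went from 2003 ± 117 to 188 ± 39.1 (log2 fold change -3.43 ± 0.13), and ALDH3A1, an aldehyde dehydrogenase, from 580 ± 63.0 to 70.3 ± 6.10 (-3.02 ± 0.11). The calcium pump gene ATP2A3 (-4.35), RP1L1 (-3.98), IGFBP5 (-3.88), the nucleotide receptor gene P2RY6 (-3.52), TP53INP1 (-3.12), the lipocalin gene APOD (-3.10), the lipoxygenase gene ALOX15 (-2.86) and SYTL2 (-2.80) completed the 12 together with FOXA1 itself. Among these 24 genes, which were chosen for passing the threshold without overlap between the groups, ATP2A3 had the highest limma adjusted p, 0.00335. Its normalized counts in FOXA1 siRNA replicates 1, 2 and 3 were 22.5, 3.79 and 5.93. Its log2 fold change ranged from -5.03 to -3.80 over its alternatives. In annotated 3' UTRs, the 7-base words GTGTGTA or TGTGTAA, which marked genes that fell, stood in ATP2A3, TP53INP1 and SYTL2, and the words AGCCTTA or AAGCCTT, which marked genes that rose, stood in GEMIN5, DTL, CDK2 and CDK6. The words of falling genes also stood in APLN, DTL, CDK6 and DSEL, which rose, and those of rising genes in P2RY6 and GPX2, which fell. Of 12992 searched genes, 3611 carried a word of falling genes and 3004 a word of rising genes. Words of falling genes stood in 3 of the 12 falls and 4 of the 11 searched rises. Those of rising genes stood in 2 and 4. The words were picked from these same fold changes, so these matches are not separate evidence.

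Of 18460 genes tested, 9571 (51.8%) changed at an adjusted p of 0.05 by limma, 4954 higher and 4617 lower with FOXA1 siRNA. At a change of at least 1.5-fold, 3529 genes remained, 1322 higher and 2207 lower, and at 2-fold 1288, of which 304 were higher and 984 lower. The values of the groups did not overlap for 57.6% of the tested genes, where chance gives 10%. The first principal component held 66.4% of the variance and separated the groups. With each library scaled to the same total, 3594 genes were higher and 5967 lower, and the median log2 fold change of all tested genes was -0.093 against 0.0039 as deposited. As deposited, the median climbed with expression level. It went from -0.19 among genes with a mean of 10 to 20 to 0.19 among those with a mean of at least 3000. The list tests were not adjusted for this trend, so small list medians in either direction may reflect it. In the authors' deposited table, 8010 genes had an adjusted p under 0.05, 4206 higher and 3804 lower, and 7848 genes were called both there and by limma, all in the same direction.

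DNA replication and mitosis genes rose together. Of 49 tested genes of the G1/S and replication list, 47 rose and 1 fell (the same counts adjusted over the list alone, median log2 fold change 0.74; camera adjusted p = 4.16e-20, and adjusted p = 0.316 with an estimated correlation). After DTL, the largest rise was that of GINS2 (1.44 ± 0.05), a subunit of the replicative helicase, and the single member that fell was CCND1, cyclin D1, which went from 7998 ± 43.7 to 2967 ± 160 normalized counts (SD, n = 3 each, -1.43 ± 0.05). Of 52 mitosis genes, 47 rose and 3 fell (48 and 3 adjusted over the list alone, median 0.52, camera adjusted p = 1.71e-18, and adjusted p = 0.387 with an estimated correlation). The mitotic kinase gene PLK1 (1.37 ± 0.06) and the kinesin gene KIF15 (1.13 ± 0.09) rose, whereas AURKA (-0.39 ± 0.07) and CDCA5 (-0.24 ± 0.06) fell. Replication-dependent histone genes went the other way, with 10 of 21 lower and 0 higher (the same adjusted over the list alone, median -0.57, camera adjusted p = 0.00687, and adjusted p = 0.387 with an estimated correlation). The median ranged from -0.77 to -0.35 over 17 alternatives, the latter without a filter on low values. Among members with a mean of at least 50, H2BC5 (-1.29 ± 0.10) and H4C14 (-0.88 ± 0.11) fell most. Most histone mRNAs lack a poly(A) tail and have near-identical copies, so their counts are uncertain.

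**Figure D2:**
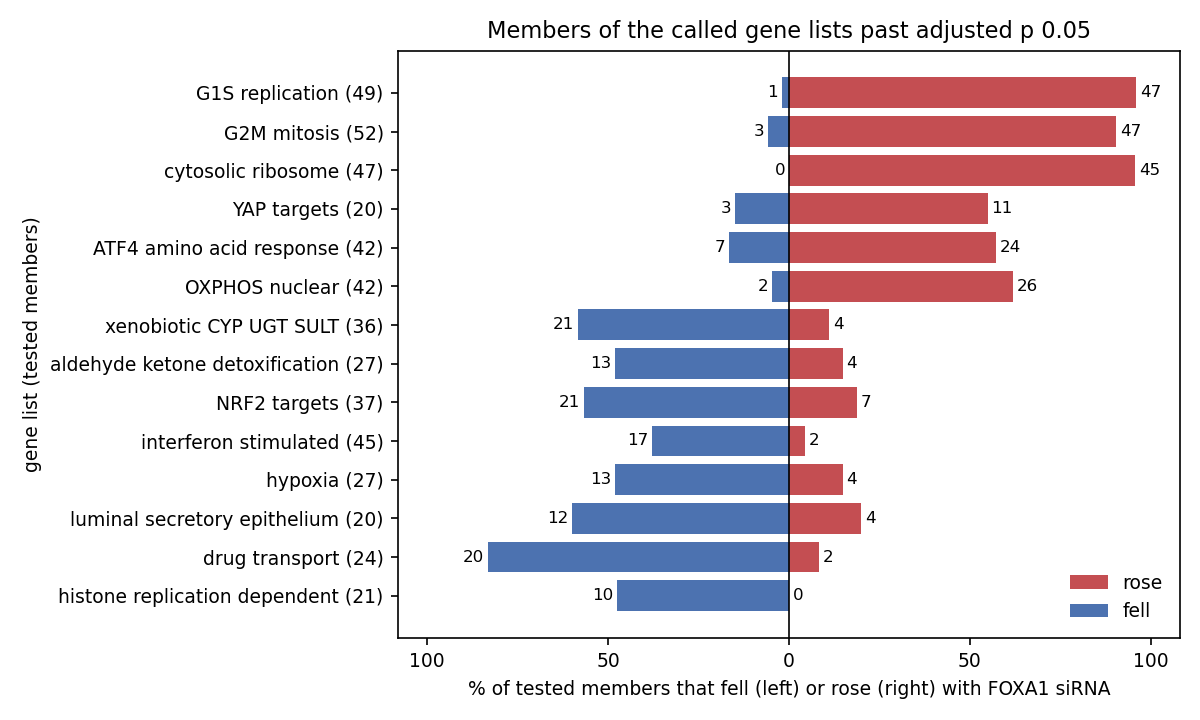
Share of the tested members of the 14 called gene lists that fell (left of 0) or rose (right of 0) with FOXA1 siRNA at an adjusted p of 0.05, in %, with the number of members at each bar and the number tested in brackets. Replication, mitosis and ribosome genes stand to the right with 47, 47 and 45 members that rose, and drug transport genes to the left with 20 that fell.

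Most ribosomal protein genes and some nuclear-encoded genes of respiration rose by smaller amounts, which were not adjusted for the trend with expression level. Of 47 cytosolic ribosomal protein genes, 45 rose and 0 fell (the same adjusted over the list alone, median 0.38, camera adjusted p = 9.98e-17, and adjusted p = 0.387 with an estimated correlation), led by RPLP2 (0.63 ± 0.05) and RPS12 (0.56 ± 0.05, or 0.36 with quantile normalization). The median of the list was 0.28 with equal totals and 0.17 with quantile normalization. These genes have many processed pseudogenes that can take part of their reads. Nuclear-encoded genes of oxidative phosphorylation rose in 26 of 42 cases and fell in 2 (the same adjusted over the list alone, median 0.20, camera adjusted p = 3.00e-04, and adjusted p = 0.615 with an estimated correlation). ATP5MC1 (0.69 ± 0.06) and the cytochrome c gene CYCS (0.40 ± 0.06) rose, and NDUFS1 (-0.38 ± 0.05) and NDUFB8 (-0.19 ± 0.06) fell. The log2 fold change of NDUFB8 was -0.29 with equal totals, and its fall did not pass without control siRNA replicate 1 (log2 fold change -0.12, adjusted p = 0.142) or with limma without its trend and robust options (adjusted p = 0.109), within a range of 3.28e-04 to 0.142 over its alternatives. The median of the list was 0.10 with equal totals and 0.12 with quantile normalization. With the latter this list no longer passed (camera adjusted p = 0.0547, the highest over its alternatives at the preset correlation, whose lowest was 2.98e-07). Mitochondrially encoded genes showed no shift as a list, with 1 of 13 higher and 4 lower (1 and 2 adjusted over the list alone, camera adjusted p = 0.690), and mitochondrial transcripts made up 7.19% to 7.68% of the normalized counts with control siRNA and 6.65% to 7.11% with FOXA1 siRNA.

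Amino acid response genes, which the transcription factor ATF4 controls, rose in 24 of 42 cases and fell in 7 (25 and 8 adjusted over the list alone, median 0.25, camera adjusted p = 0.00265, and adjusted p = 0.387 with an estimated correlation). The median was 0.15 with equal totals. ATF3 (1.37 ± 0.13) and SLC7A5 (0.97 ± 0.05), the large neutral amino acid transporter, rose. DDIT4 (-1.32 ± 0.05), an inhibitor of mTORC1, and GDF15 (-0.99 ± 0.08) fell. Among targets of YAP, 11 of 20 rose and 3 fell (the same adjusted over the list alone, median 0.28, camera adjusted p = 0.00687, and adjusted p = 0.387 with an estimated correlation). The median of that list was 0.19 with equal totals. DLC1 (0.98 ± 0.19) and CCN1 (0.73 ± 0.12) rose, and NT5E (-0.65 ± 0.05) and ARHGEF17 (-0.24 ± 0.07) fell. The fall of ARHGEF17 did not pass with limma without its trend and robust options (adjusted p = 0.0687, the highest over its alternatives, whose lowest was 3.56e-04). Quantile normalization ended the call of the YAP list too (camera adjusted p = 0.0547, the highest over its alternatives at the preset correlation, whose lowest was 1.82e-04).

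Of 24 drug transporter genes, 20 fell and 2 rose (the same adjusted over the list alone, median -0.51, camera adjusted p = 6.39e-07, and adjusted p = 0.199 with an estimated correlation). ABCA1, the cholesterol exporter, fell from 183 ± 3.39 to 32.0 ± 6.94 normalized counts (SD, n = 3 each, -2.50 ± 0.18), and SLC22A18 fell by 1.91 on the log2 scale. The 2 that rose were the folate transporter gene SLC46A1 (0.52 ± 0.08) and ABCG2, the breast cancer resistance protein, which went from 954 ± 22.1 to 1104 ± 71.3 (0.21 ± 0.06, limma adjusted p = 0.00682). The rise of ABCG2 did not pass with equal totals (log2 fold change 0.11, adjusted p = 0.140) or quantile normalization (adjusted p = 0.0545), within a range of 0.00529 to 0.140 over its alternatives. Genes of cytochromes P450, UDP-glucuronosyltransferases and sulfotransferases fell in 21 of 36 cases and rose in 4 (22 and 4 adjusted over the list alone, median -0.19, camera adjusted p = 0.00265, and adjusted p = 0.307 with an estimated correlation). With equal totals the median was -0.28. SULT1A1 (-2.54 ± 0.22), whose reads could be shared with its close paralogs, and CYP4F3 (-2.01 ± 0.16) fell, while CYP24A1 (0.98 ± 0.19) and SULT1E1 (0.93 ± 0.15) rose.

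Of 37 targets of NRF2, the regulator of the antioxidant response, 21 fell and 7 rose (the same adjusted over the list alone, median -0.22, camera adjusted p = 6.99e-04, and adjusted p = 0.387 with an estimated correlation). Its members AKR1C2 and AKR1C3 fell, and SRXN1 (0.38 ± 0.05) and TRIM16 (0.61 ± 0.05) rose. Aldehyde and ketone detoxification genes fell in 13 of 27 cases and rose in 4 (13 and 5 adjusted over the list alone, median -0.21, camera adjusted p = 0.0159, and adjusted p = 0.456 with an estimated correlation). Besides ALDH3A1 (-3.02 ± 0.11), the aldo-keto reductase genes AKR1C1 (-1.11 ± 0.10), AKR1C2 (-1.49 ± 0.08) and AKR1C3 (-1.74 ± 0.11) fell. These 3 reductase genes are paralogs, and the counting could exchange reads between them, most of all between AKR1C1 and AKR1C2, which are near-identical. ALDH18A1 (0.37 ± 0.06) and ALDH16A1 (0.33 ± 0.07) rose. NQO1, another NRF2 target, was at 5123 ± 156 and 5325 ± 95.2 normalized counts (SD, n = 3 each, log2 fold change 0.06, limma adjusted p = 0.319), with the opposite sign under equal totals and under quantile normalization, where it passed as lower (adjusted p = 0.0406, within a range of 0.0406 to 0.567 over its alternatives).

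The cystine and glutathione genes did not move as a list. Of 41 tested, 13 rose and 14 fell (14 and 15 adjusted over the list alone, camera adjusted p = 0.951). Their median log2 fold change was 0.0013 and their mean -0.12. SLC7A11, the transport subunit of xCT that sulfasalazine blocks, was at 1185 ± 60.2 with control siRNA and 1118 ± 65.7 with FOXA1 siRNA (SD, n = 3 each, -0.08 ± 0.06, limma adjusted p = 0.270). It passed as lower under equal totals (adjusted p = 0.0150) and quantile normalization (adjusted p = 0.0406), within a range of 0.0150 to 0.586 over its alternatives. SLC3A2, its partner subunit, rose (0.78 ± 0.05). GCLC, the catalytic subunit of glutamate-cysteine ligase, fell from 2058 ± 37.0 to 1490 ± 77.0 (-0.47 ± 0.05, limma adjusted p = 4.15e-08). GCLM, the regulatory subunit, did not pass (-0.20 ± 0.10, limma adjusted p = 0.0864), but it did under equal totals (adjusted p = 0.0119), without FOXA1 siRNA replicate 3 (0.0293) and with limma-voom (0.0479), within a range of 0.0119 to 0.302 over its alternatives. PRDX6 rose (0.95 ± 0.05), and GGT6 fell (-1.18 ± 0.10) besides GPX2 (-3.43 ± 0.13). Ferroptosis regulators likewise went both ways, with 22 of 50 higher and 14 lower (the same adjusted over the list alone, median 0.10, mean -0.09, camera direction up, adjusted p = 0.740). GPX4, which reduces lipid hydroperoxides, was at 1497 ± 54.2 and 1585 ± 74.7 (0.08 ± 0.06, limma adjusted p = 0.230, with the opposite sign under equal totals). AIFM2, also called FSP1, fell (-0.99 ± 0.15) besides ALOX15 (-2.86 ± 0.24), and ALOX5 rose (1.01 ± 0.13).

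Markers of secretory epithelium fell in 12 of 20 cases and rose in 4 (12 and 5 adjusted over the list alone, median -0.43, camera adjusted p = 0.0221, and adjusted p = 0.387 with an estimated correlation). Besides SPDEF, AGR2, a protein disulfide isomerase of secretory cells, fell from 962 ± 87.3 to 254 ± 15.9 normalized counts (SD, n = 3 each, -1.92 ± 0.08), while ESR1 (0.73 ± 0.15) and KRT8 (0.58 ± 0.04) rose, KRT8 by only 0.18 with quantile normalization. Among genes with a mean of at least 50 alone, the list no longer passed (median -0.29, camera adjusted p = 0.0551). This was the highest over its alternatives at the preset correlation, whose lowest was 0.00192. Basal squamous genes went both ways, with 11 of 25 higher and 7 lower (the same adjusted over the list alone, camera adjusted p = 0.348). SFN (1.14 ± 0.05) and KRT17 (1.01 ± 0.05) rose, and KRT15 (-0.84 ± 0.04), SOX2 (-0.73 ± 0.06) and TP63 (-0.40 ± 0.05), the transcription factor of basal cells, fell. Squamous differentiation genes rose in 2 of 20 cases and fell in 5 (the same adjusted over the list alone, median 0.19, mean -0.02, camera direction down, adjusted p = 0.968). Of 27 epithelial junction genes, 15 rose and 8 fell (the same adjusted over the list alone, camera adjusted p = 0.450), and of 28 mesenchymal genes, 9 rose and 8 fell (9 and 10 adjusted over the list alone, median -0.06, mean -0.10, camera direction up, adjusted p = 0.968). CD44, the hyaluronan receptor, did not pass (0.09 ± 0.04, limma adjusted p = 0.0792), and its sign was the opposite under equal totals and under quantile normalization, where it passed as lower (adjusted p = 0.00166). It passed as higher without a filter on low values (adjusted p = 0.0449), within a range of 0.00166 to 0.814 over its alternatives. Stem cell markers rose in 6 of 10 cases and fell in 3 (7 and 3 adjusted over the list alone, median 0.20, mean -0.15, camera direction up, adjusted p = 0.937). KLF4 (log2 fold change 0.57) and SOX9 (0.51) were among the stem cell markers that rose. The largest fall among these markers was of NGFR (-2.17 ± 0.08), and ALDH1A3 also fell (-1.14 ± 0.04).

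Interferon-stimulated genes fell in 17 of 45 cases and rose in 2 (16 and 2 adjusted over the list alone, median -0.24, camera adjusted p = 0.0162, and adjusted p = 0.770 with an estimated correlation). BST2 (-1.42 ± 0.17) and IRF9 (-0.91 ± 0.16) fell, and TRIM25 (0.74 ± 0.05) and DTX3L (0.22 ± 0.09) rose. The list did not pass without FOXA1 siRNA replicate 2 (camera adjusted p = 0.217, median -0.087) or with edgeR (0.0820), within a range of 0.00239 to 0.217 over its alternatives. The rise of DTX3L was lost in 7 of its 19 alternatives, among them those without control siRNA replicate 2, control siRNA replicate 3 or FOXA1 siRNA replicate 3 (log2 fold change 0.11), with adjusted p from 0.00496 to 0.263. With equal totals its log2 fold change was 0.12. Hypoxia genes fell in 13 of 27 cases and rose in 4 (13 and 5 adjusted over the list alone, median -0.26, camera adjusted p = 0.00405, and adjusted p = 0.615 with an estimated correlation). The adenylate kinase gene AK4 (-1.17 ± 0.05), and DDIT4 fell, while P4HA2 (0.59 ± 0.08) and EGLN3 (0.41 ± 0.10) rose. The rise of EGLN3 did not pass with limma without its trend and robust options (adjusted p = 0.0509, the highest over its alternatives, whose lowest was 5.42e-08).

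Other metabolic lists did not pass. Of 20 genes of the pentose phosphate pathway and NADPH supply, 11 rose and 5 fell (the same adjusted over the list alone, camera adjusted p = 0.0658). RPIA and PRPS2 (1.31 ± 0.07) rose and HK1 (-0.42 ± 0.05) fell. This list passed in 4 of its 17 alternatives, among them those without control siRNA replicate 3 (0.0277) or FOXA1 siRNA replicate 1 (0.0325), with adjusted p from 0.00316 to 0.459. Glycolysis genes rose in 5 of 25 cases and fell in 9 (the same adjusted over the list alone, camera adjusted p = 0.429). SLC16A1 (1.70 ± 0.05), the lactate transporter MCT1, and LDHB (0.45 ± 0.05, or 0.28 with quantile normalization) rose, and PGAM1 (-1.02 ± 0.04) and ENO2 (-0.66 ± 0.14) fell. With quantile normalization the glycolysis list passed as lower (adjusted p = 0.0164, within a range of 0.0164 to 0.703). Of 37 genes of glutamine use and the citric acid cycle, 18 rose and 6 fell (19 and 6 adjusted over the list alone, camera adjusted p = 0.108). SUCLG2 (0.82 ± 0.08) and ACO1 (0.67 ± 0.07) rose, and PDHA1 (-1.27 ± 0.06), a pyruvate dehydrogenase subunit, and GPT (-0.96 ± 0.24) fell. Without a filter on low values that list passed as higher (adjusted p = 0.0177, within a range of 0.0177 to 0.710). Fatty acid synthesis genes rose in 7 of 24 cases and fell in 8 (7 and 9 adjusted over the list alone, camera adjusted p = 0.485), and fatty acid oxidation genes in 5 and 12 of 26 (the same adjusted over the list alone, camera adjusted p = 0.309). Of 25 cholesterol synthesis genes, 10 rose and 8 fell (the same adjusted over the list alone, camera adjusted p = 0.811), with PMVK (0.57 ± 0.10) among the rises and CYP51A1 (-1.15 ± 0.06) among the falls.

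Stress and signalling lists were mixed and none of the following passed. Genes of the unfolded protein response rose in 12 of 27 cases and fell in 7 (13 and 7 adjusted over the list alone, camera adjusted p = 0.461), with SSR3 (0.73 ± 0.05) higher and SEL1L (-1.25 ± 0.05) lower. Targets of p53 rose in 6 of 28 cases and fell in 10 (7 and 10 adjusted over the list alone, camera adjusted p = 0.490). CCNG1 (1.28 ± 0.06) and AEN (1.00 ± 0.09) rose and BTG2 (-1.27 ± 0.06) fell besides TP53INP1. The median of the p53 list was 0.0024 and its mean -0.18. Of 32 apoptosis genes, 11 rose and 10 fell (the same adjusted over the list alone, camera adjusted p = 0.943), with a median of 0.04 and a camera direction of down. Genes of antigen presentation by MHC class I rose in 3 of 17 cases and fell in 5 (the same adjusted over the list alone, camera adjusted p = 0.595). Cytokine genes and other targets of NF-kB rose in 3 of 24 cases and fell in 8 (the same adjusted over the list alone, camera adjusted p = 0.744), with a median of 0.07 and a mean of -0.16. Immediate early genes rose in 15 of 32 cases and fell in 8 (15 and 9 adjusted over the list alone, camera adjusted p = 0.290), with DUSP8 (1.41 ± 0.18), a MAP kinase phosphatase, higher and ETV4 (-1.05 ± 0.12) lower. Of 22 genes of EGFR and related receptors and ligands, 8 rose and 7 fell (the same adjusted over the list alone, camera adjusted p = 0.989), with a median of -0.06 and a mean of 0.05. EPGN (1.19 ± 0.09), a ligand of EGFR, rose and LRIG1 (-0.95 ± 0.06) fell. Genes of TGF-beta and BMP signalling rose in 7 of 29 cases and fell in 13 (the same adjusted over the list alone, camera adjusted p = 0.108), and those of WNT and NOTCH signalling in 6 and 13 of 31 (the same adjusted over the list alone, camera adjusted p = 0.108). ID1 (0.97 ± 0.07) rose and LTBP2 (-1.26 ± 0.05) and LGR4 (-0.87 ± 0.05) fell. Of 13 genes of the RNA interference machinery, 3 rose and 4 fell (the same adjusted over the list alone, camera adjusted p = 0.989), with a median of 0.01 and a mean of -0.03. XPO5 (0.64 ± 0.06) rose and TNRC6B (-0.75 ± 0.06) fell.

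The words also stood in the 3' UTRs of other genes named here, whichever way these genes went. GTGTGTA or TGTGTAA alone stood in AKR1C2, ABCA1, AIFM2, PGAM1, ENO2, AK4, NDUFB8, CCND1, AURKA, BTG2, NT5E, LGR4, NGFR, ALDH1A3, GCLC and AKR1C1, which fell, in EGLN3, ACO1, CYCS, DTX3L and DUSP8, which rose, and in NQO1 and CD44, which did not pass. AGCCTTA or AAGCCTT alone stood in FOXO1, P4HA2, GINS2, CCNG1, TRIM25, CCN1, DLC1 and SOX9, which rose, and in ARHGEF17, which fell. Words of both kinds stood in FOXN3, DDIT4, SEL1L, CYP51A1, PDHA1, NDUFS1, CDCA5, H4C14, TNRC6B and TP63, which fell, in SRXN1, PRPS2, SLC16A1 and SUCLG2, which rose, and in SLC7A11 and GCLM, which did not pass.

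Markers of other cell types were scarce, as the culture is of a single line. Of 15 fibroblast markers, 5 were tested, 3 of which fell and 0 rose (4 and 0 adjusted over the list alone, camera adjusted p = 0.0697). The fibroblast list passed as lower without control siRNA replicate 2 (adjusted p = 0.0483) and without FOXA1 siRNA replicate 1 (0.0389), within a range of 0.0389 to 0.252 over its alternatives. Of 20 immune markers, 2 were tested and neither passed. The only endothelial marker tested, CDH5, fell from 554 ± 15.1 to 288 ± 10.3 normalized counts (SD, n = 3 each, -0.94 ± 0.08). No list passed camera with an estimated correlation after adjustment, and 3 of 40 did so at an unadjusted p under 0.05. Fry, which asks whether the genes of a list move on balance in a single direction, passed 28 of the 40.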

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

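Limma-voom and the count over protein-coding genes alone were chosen after seeing the data. FOXA1 stayed lower and past the threshold under its 19 alternatives (log2 fold change -2.91 to -2.72). Of 9571 genes changed, 9362 were also called with edgeR and 8467 with DESeq2. Without each sample in turn, 8560 to 9180 genes changed, and with an adjusted p of 0.01, 7498. The replicate number as a block gave 9332, though the labels do not say whether the numbers pair the samples. Deviations from the group mean showed no sign of it in libraries of the same number (correlations -0.010, 0.011 and -0.011). With a mean of at least 50, 1436 genes were lower by 1.5-fold, as fewer genes were tested. Camera with an estimated correlation called 0 lists and fry 28, against 14. Fry asks another question, whereas camera with an estimated correlation asks the same one, and all 14 calls were lost with it. Correlation alone does not account for this loss. The estimated correlation was 0.0063 for drug transport and -8.98e-04 for the cytochrome P450, UDP-glucuronosyltransferase and sulfotransferase list, both under the preset 0.01. Their unadjusted camera p still went from 6.39e-08 to 0.00497 and from 4.75e-04 to 0.0153. The naming rule picked 172 genes besides FOXA1, not all of which are described above. For these, 3230 of 3267 values kept their direction and side of the threshold, and for the called lists 246 of 266 did. The exceptions concerned 16 genes. KLK5, CXCL8, HES4, MT-ND1 and MT-ATP6, not described above, were among them and lost their calls in some alternatives.

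Under equal totals GPX4 (-0.015), NQO1 (-0.042) and CD44 (-0.012) reversed, and under quantile normalization NQO1 (-0.11) and CD44 (-0.16). For lists that were not called, the direction of the test reversed as follows, with the list median given. Without a filter on low values these were the mesenchymal (-0.065), apoptosis (0.043) and RNA interference (0.012) lists, and with a mean of at least 50 the EGFR list (-0.086). Under equal totals it was squamous differentiation (0.093). Under quantile normalization these were the basal squamous (-0.0088), epithelial junction (0.013), mesenchymal (-0.032), ferroptosis (0.022), unfolded protein (0.010), EGFR (-0.074) and stem cell (0.17) lists. With the block these were squamous differentiation (0.19), mesenchymal (-0.060) and RNA interference (0.012). With edgeR these were ferroptosis (0.086), apoptosis (0.025) and stem cell (0.19), and with fry ferroptosis (0.10), EGFR (-0.062) and stem cell (0.20). Among protein-coding genes they were mesenchymal (-0.060) and EGFR (-0.062). With a sample left out, 5 of these lists reversed in some cases, and their medians ranged from 0.14 to 0.25 (squamous differentiation), -0.11 to -0.022 (mesenchymal), -0.037 to 0.086 (apoptosis), -0.094 to -0.024 (EGFR) and 0.011 to 0.041 (RNA interference). The cause was not tested. DESeq2 and limma-voom were not run for the lists.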

Other observations

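The test of GT repeats was chosen only after the result was seen. The real split of the 6 samples called 9571 genes, and the highest of the other splits called 1. With 10 splits, 1 of them as large as the real one, the share cannot fall under 0.05.

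The replication, mitosis and cytosolic ribosome lists passed as higher with the preset correlation, and none of them did with an estimated correlation (adjusted p = 0.316, 0.387 and 0.387). With trends on transcript length and GC content removed, the lowest of the 3 medians was 0.42, which argues against these as the whole cause. Among members whose 3' UTRs lacked GTGTGTA, TGTGTAA, AGCCTTA and AAGCCTT, the lowest median was 0.35. An siRNA seed match is pairing of the first bases of a guide strand with other transcripts. The value argues against direct seed matches through these words as the whole cause. Other seed sites and indirect effects of silenced genes were not tested. Under 3 scalings the lowest median was 0.17, of the ribosome list with quantile normalization, between the bounds set for either reading, so scaling cannot be told apart from a rise for that list. A change in the cells after FOXA1 knockdown stays open.

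Falls of at least 1.5-fold outnumbered rises 1.67 to 1 (95% interval 1.56 to 1.79). Without control siRNA replicate 2 the ratio was 1.54. The intervals given here treat genes as independent and leave out the spread between samples. Among genes with a mean of at least 300 the ratio was 0.885 (0.790 to 0.990), so the excess of falls lay in genes with fewer reads, which does not show why. Among genes whose 3' UTRs lacked GTGTGTA, TGTGTAA, AGCCTTA and AAGCCTT the ratio was 1.61, against 1.55 among all searched genes. It was 2.58 among carriers of the first 2 words and 0.81 among carriers of the last 2. The words were picked from these same fold changes, so neither of these 2 ratios is separate evidence. The value of 1.61 argues against direct pairing through these words as the whole cause. Other seed sites and indirect effects of silenced genes were not tested. The ratio was 3.10 with equal totals, 1.78 with recomputed factors and 1.13 with quantile normalization, which forces equal distributions, so scaling cannot be told apart.

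Of 16142 words in 3' UTRs, 5 marked lower and 7 higher log2 fold changes past the bound. All 5 of the former contain GTGTA and all 7 of the latter contain GCCT, so the words of a direction overlap and are not separate signals. The 2176 genes with GTGTGTA were on average lower than others (z = -13.3, shift -0.20), with 40.9% called lower and 23.6% higher against 24.6% and 32.9% of the rest, and the 1530 genes with AGCCTTA were higher (z = 8.95, shift 0.15), with 41.9% called higher and 21.6% lower. GTGTGTA also stood in 2 of 5 annotated FOXA1 transcripts, as it does in 14.8% of genes of similar length, while TGTGTAA stood in 0 of 5. In the longest transcript the GTGTGTA site lay in the coding sequence. The GT repeat had z = -1.56 as GTGTGTG and z = -4.36 as TGTGTGT, both short of the bound of 4.66. This argues against GT repeats as the whole cause. An siRNA guide that pairs through its seed with other transcripts may account for the falls, and the loss of such pairing by the control siRNA for the rises, but the siRNA sequences are not given and a microRNA of the cells was not excluded. Of 7702 searched genes with none of GTGTGTA, TGTGTAA, AGCCTTA and AAGCCTT, 56.5% were called, against 58.7% of all searched genes. Direct seed pairing through these words would leave at least 4353 of the 7628 calls among searched genes open. Not all calls among carriers went with their words. Of 3611 carriers of the first 2 words 62.1% were called, and 977 rose. Of 3004 carriers of the last 2 words 61.9% were called, and 707 fell. Both kinds stood in 1325 genes. Genes with other words past the bound were not taken out.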
